A study of Homo sapiens with 8 samples.

How the data were processed

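RNA of HEK293T cells transfected for 48 h with Msi1 or GFP was compared on 8 two-colour Agilent whole-genome arrays. Per the labels, there were 2 biological replicates, and one slide held one biological sample against its control on 4 arrays with dye swaps. Each slide was therefore taken as 1 replicate, and its 4 arrays as technical repeats. The 2 slides were scanned on different days, so slide, scan day and replicate cannot be told apart, but each array held both Msi1 and GFP. The values of both replicates are plotted for the named genes.

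Per the file headers, spot intensities were extracted with Agilent Feature Extraction and are deposited as mean spot signal and median local background in each channel, with no normalization. The version is 9.5 per the submitters' processing notes, which also name limma. Agilent's processed signals are deposited intensities after Agilent's own background subtraction, detrending and linear and lowess dye normalization, per the file headers. The value table of the series holds the authors' log2 ratios, whose making was settled by comparison with the scanner values. They matched the values computed here (normexp and loess) at correlations of 0.9999 or more in size with slopes near 1.00, and were already turned to Msi1 over GFP. Their medians lay between 0.000171 and 0.00625.

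Here the background was corrected with normexp (offset 50) on mean signal and background median, and each array was normalized by loess in limma 3.58.1 under R 4.3.3. Control spots and spots with outlier flags had weight 0 in loess and were then left out, with between 98 and 471 flagged spots per array, and 0 spots were saturated. Ratios were turned to Msi1 over GFP and spots of one probe were averaged. Each replicate value was the mean of its 2 orientation means, so that dye effects equal on its arrays cancel. A probe was kept if it was well above background in the Msi1 channel on at least 4 arrays or in the GFP channel on at least 4 arrays, which left 27936 of 41000 probes. The brightest probe stood for each gene. None of the named genes lacked signal above background in either channel.

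Probe names are those of the array design. Through the accession 23680 probes received the current symbol of a RefSeq table of GRCh38.p14, 2802 already had it, 1128 had an older symbol and 13390 kept the name in the files. Some named genes are therefore known on the array by older names, as TMEPAI for PMEPA1, FAM129B for NIBAN2 and KIAA1627 for METTL14. Probe positions are those of the files, on hg18. Of the 20667 genes and transcripts tested, 13945 had a symbol from the table.

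Each gene was tested with limma (lmFit with an intercept, then eBayes) on n = 2 replicate values, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The moderated test had 4.12 degrees of freedom. The same test was run on the dye contrast. For 30 gene lists fixed before the data were examined, camera was run on the moderated statistics with a preset correlation of 0.01, adjusted over the lists, and calls were also counted adjusted over the list alone. Camera was also run on the 8 arrays themselves with slide and dye fitted, over the 20350 genes measured on all arrays. There the correlation was estimated from the residuals, and the gene statistics too had technical arrays as their unit. These array residuals are technical, so that estimate does not hold the spread between cultures. Of the 12 lists called with the preset correlation, 4 held in this second test, which differs from the first in unit as well as in correlation. On the same 8 arrays fry, which asks whether a list's genes move one way on balance, called 25 lists.

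The genes named were set by a rule fixed before the data were examined. MSI1, MSI2, NUMB and CDKN1A were always named. The 12 genes with the highest and the 12 with the lowest mean log2 ratio were named among those past the threshold with a gene symbol (no clone or open reading frame names) and the same sign on all 8 arrays. For each list up to 4 members past the threshold with the largest changes were named, or the 2 largest where none passed. The rule also had a way to fill a direction with fewer than 12 genes, which was not needed. One gene that the rule names is not reported here.

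The pipeline was tested on simulated data of 2 replicates of 4 arrays with 20667 genes, of which 200 were changed. It called 10.4% of the genes changed 1.5-fold, 83.6% of those changed 2-fold and 95.5% of those changed 4-fold, each in the right direction, with 11 false calls among 137. Genes were simulated as independent, with variances drawn from limma's own fitted prior and a common technical SD. The assumptions of the test thus held by construction, and these rates may not carry over to the real arrays. A dye effect simulated in 200 other genes gave 0 calls for Msi1. It was equal on all arrays and so cancelled by construction, which checks the computation only and not real dye effects. Alternatives were no background subtraction, Agilent's processed signals, median centring, the authors' values, no or a stricter filter on dim probes, other units of replication, single dye orientations, each array or replicate left out, a variance trend with robust moderation, the mean of all probes and a threshold of 0.10. Another background fit for one array, centring on spike-in controls and the dimmest probe of each gene were added after the data were seen. Probe sequences were not used here, and no genome was searched. Figures were drawn with matplotlib 3.10.9.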

Results

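RNA levels were compared between HEK293T cells transfected to overexpress Musashi1 (Msi1), an RNA-binding protein known from neural progenitor cells, and HEK293T cells transfected to overexpress green fluorescent protein (GFP). HEK293T is a human embryonic kidney line that is widely used because it takes up plasmids readily. Both proteins carried a biotin acceptor peptide tag, and the cells were collected 48 h after transfection. Msi1 and GFP RNA were hybridised together on 8 two-colour arrays, 4 for each of 2 biological replicates. In each replicate Msi1 was labelled with Cy5 on 2 arrays and with Cy3 on the other two. Each array held 41000 distinct probes outside the controls. Between 62.3% and 75.1% of its spots were well above background in Cy3, and between 55.4% and 68.1% in Cy5. The number of replicates, n = 2, limits the precision of every value below. After loess, changes in the main comparison are relative to the bulk of genes of like brightness on the same array.

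The level of MSI1 itself was examined first, as a check of the labels. Its probe, at chromosome 12, 119264593 to 119264652 on hg18, gave a log2 ratio of Msi1 over GFP of 0.26 ± 0.15 (SD, n = 2), or 1.19-fold, and the ratio was above 0 on 8 of 8 arrays. The change was not past the threshold by limma (adjusted p = 0.129). Its log2 ratio was 0.39 with Agilent's processed signals (adjusted p = 0.155) and 0.50 when each replicate was centred on its spike-in controls (adjusted p = 0.061). The part of MSI1 that the construct carried is not given in the sources used here, so the probe may lie outside it, and overexpression of Msi1 was not shown by these arrays. MSI2, the close relative of MSI1, stood at a log2 ratio of 0.37 ± 0.05 (SD, n = 2; adjusted p = 0.052) at its brightest probe and at 0.49 ± 0.11 at its other probe. MSI2 passed the threshold in 17 of 28 alternatives, among them no background subtraction (adjusted p = 0.0493), the strict filter on dim probes (0.0285) and the mean of all probes (0.0377). The 17 also include the threshold of 0.10, where its adjusted p by limma stayed at 0.052, and fits with technical arrays as the unit. Leaving out either replicate gave no p-value. NUMB, an inhibitor of Notch signalling whose mRNA is a known Msi1 target, rose 1.4-fold (log2 0.48 ± 0.09, SD, n = 2; adjusted p = 0.0396) and was higher on 7 of 8 arrays. The NUMB call was lost without array 4 of replicate 2 (adjusted p = 0.0742) and with only the arrays that had Msi1 in Cy5 (log2 0.23, adjusted p = 0.193). It was also lost with Agilent's processed signals (adjusted p = 0.112), median centring (0.0784), no filter on dim probes (0.0594) and a variance trend with robust moderation (0.0766), and over all alternatives the log2 ratio lay between 0.23 and 0.74. CDKN1A, which encodes the cell cycle inhibitor p21 and is another known Msi1 target, did not pass the test (log2 0.21 ± 0.21, SD, n = 2; adjusted p = 0.245).

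Among called genes with a gene symbol and the same sign on all 8 arrays, the largest increases were at probes for PMEPA1, SDE2, LSMEM1, NFYA and IL23A. The probe of PMEPA1, which encodes an inhibitor of TGF-beta signalling, stood 9.35-fold higher (log2 3.22 ± 1.28, SD, n = 2), with log2 ratios of 4.13 and 2.32 in the 2 replicates. SDE2 rose 6.76-fold (log2 2.76 ± 0.13, SD, n = 2) and LSMEM1 3.85-fold (1.94 ± 0.50). NFYA, a subunit of the CCAAT-binding factor NF-Y, rose 3.74-fold (1.90 ± 0.26), and IL23A, which encodes a subunit of interleukin-23, rose 3.42-fold (1.77 ± 0.56). The zinc finger genes ZNF200, ZNF614 and ZNF256 rose 3.17-fold, 3.12-fold and 2.99-fold, and the homeobox gene PKNOX1 rose 3.06-fold. TXNIP, which encodes a thioredoxin-binding protein, rose 2.97-fold (1.57 ± 0.18), PLK3, a stress-responsive kinase gene, 2.93-fold (1.55 ± 0.28), and METTL14, a subunit of the m6A methyltransferase, 2.81-fold (1.49 ± 0.27). These 12 genes had adjusted p between 0.0227 and 0.0377 by limma and were higher on 8 of 8 arrays. PMEPA1 and NFYA each had another measured probe, with log2 ratios of only 0.26 and 0.15, and those of ZNF614 and PKNOX1 stood at means of 0.62 and 0.61. With the dimmest probe the calls of these 4 genes were lost (adjusted p = 0.101, 0.237, 0.0614 and 0.112), and without a filter on dim probes those of PMEPA1, LSMEM1, IL23A and ZNF614 (adjusted p = 0.0773, 0.056, 0.0644 and 0.0674). The PMEPA1 call was also lost without array 4 of replicate 2 (adjusted p = 0.0517) and with a variance trend and robust moderation (0.0508).

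By the same rule the largest decreases were at probes for YPEL4, GBP4, CLDN3, NIBAN2 and SMC3. Their signals fell 44.2-fold, 29.1-fold, 28.8-fold, 23.1-fold and 19.9-fold in Msi1, with log2 ratios of -5.47 ± 1.46, -4.86 ± 1.46, -4.85 ± 1.92, -4.53 ± 0.50 and -4.31 ± 1.25 (SD, n = 2). CLDN3 encodes a tight junction protein, GBP4 an interferon-inducible GTPase and SMC3 a cohesin subunit. The placental growth hormone gene GH2 followed at 15.3-fold lower, ANKLE1 at 13.2-fold, the ephrin gene EFNB3 at 9.15-fold, GPR25 at 6.72-fold, FCRLB at 6.60-fold, the homeobox gene TLX2 at 4.92-fold and the heat shock gene HSPA6 at 4.85-fold. GH2 and HSPA6 have near-identical relatives whose transcripts these probes could also bind. Without array 4 of replicate 2 the calls of GH2, ANKLE1 and GPR25 were lost (adjusted p = 0.0509 and 0.0545 for GH2 and ANKLE1, and at the threshold for GPR25), at nearly unchanged log2 ratios of -3.94, -3.70 and -2.75. Agilent's processed signals lost the calls of GH2, EFNB3, GPR25 and TLX2 (adjusted p = 0.0532, 0.0521, 0.0695 and 0.0589), no filter on dim probes lost those of all but NIBAN2 (adjusted p between 0.0565 and 0.0904), and a variance trend with robust moderation lost all 12 (adjusted p between 0.149 and 0.27). All 12 were lower on 8 of 8 arrays, with adjusted p between 0.0227 and 0.0456 by limma. In 6 of them, YPEL4, CLDN3, NIBAN2, EFNB3, FCRLB and TLX2, another probe of the same gene was measured, and it stood at log2 ratios of only -0.07, -0.02, -0.05, -0.18, 0.07 and 0.00. Among the 47 genes that were at least 2-fold lower, 12 had another measured probe, and at 0 of these 12 did the other probes keep 50% or more of the change.

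**Figure D1:**
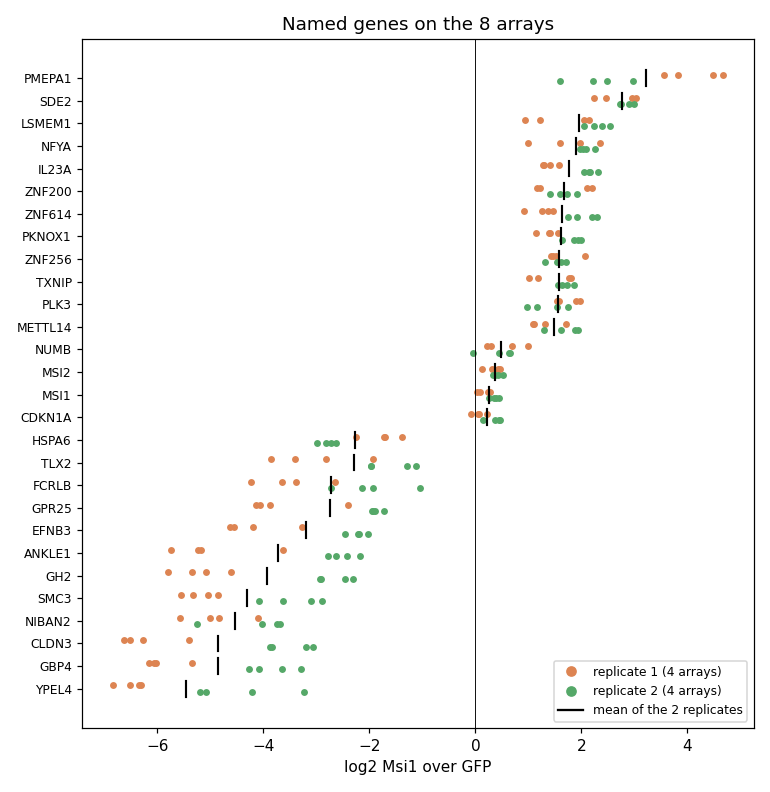
The log2 ratio of Msi1 over GFP on the 8 arrays for the 28 genes named by the fixed rule, with arrays of replicate 1 in orange, those of replicate 2 in green and the mean of both replicates as a black bar. YPEL4 lay lowest, with a mean of -5.47, and PMEPA1 highest, with 3.22.

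Across the 20667 genes and transcripts tested, 1377 were higher in Msi1 and 321 were lower at an adjusted p of 0.05 (limma, n = 2). At least 2-fold changes were seen for 150 of the higher and 47 of the lower genes. The same sign on all 8 arrays was found for 1504 of the 1698. The median log2 ratio was 0.61 among the higher and -0.50 among the lower genes. Without array 4 of replicate 1 there were 2936 called genes in place of 1698, with 832 lower, and with another background fit for that array 558 were lower. The lowest adjusted p was 0.0227, so with 2 replicates the calls lay near the threshold. With a variance trend and robust moderation 473 genes were higher and 0 lower, against 6396 genes in all at an unadjusted p under 0.05 in the fit without them. Of the called genes 81.1% were higher. This share was 52.8% with arrays as independent units, 57.1% with slide as a random block, 60.3% with only the arrays that had Msi1 in Cy5 and 68.5% with the strict filter, and 97.1% when each replicate was centred on its spike-in controls, which moved the median of all genes to 0.24.

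**Figure D2:**
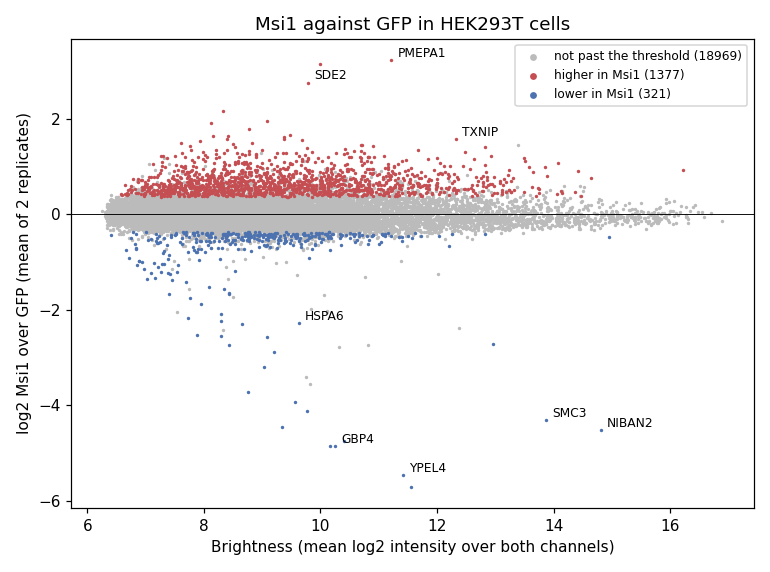
The log2 ratio of Msi1 over GFP, as the mean of 2 replicates, against brightness, as mean log2 intensity over both channels, for 20667 genes and transcripts. Red points are the 1377 genes higher in Msi1, blue points the 321 lower, and grey points did not pass the threshold.

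Probes of one gene often differed. Of the 1698 called genes, 717 had another measured probe, and in 553 of them, or 77.1%, all other probes moved in the direction of the brightest one. For genes at least 2-fold higher the median log2 ratio was 1.19 at the brightest probe and 0.33 at the others, over 65 genes. For the 12 genes at least 2-fold lower it was -2.20 and -0.03. When the dimmest measured probe stood for each gene in place of the brightest, 983 genes passed the threshold, of which 852 were among the 1698. Of the 1698 only the 717 with another measured probe could change probe, so this overlap was in part fixed by construction. The comparison with the dimmest probe was added after the disagreement was seen.

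**Figure D3:**
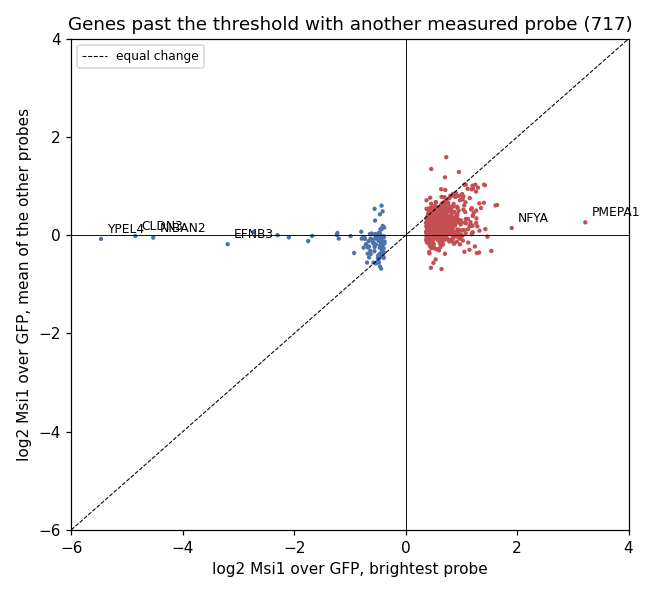
For the 717 called genes with another measured probe, the mean log2 ratio of the other probes (vertical axis) against that of the brightest probe (horizontal axis), with red for higher and blue for lower genes and a dashed line for equal change. The strongly lower genes YPEL4 and CLDN3 lie near 0 on the vertical axis, at -0.07 and -0.02.

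As lists, genes of the cell cycle, of the early response to stimuli and known p53 targets were higher in Msi1. Of 54 measured genes of the G2 and M phases, 19 rose and 0 fell, among them G2E3 (2.52-fold), TMPO (2.41-fold), KIF23 (1.92-fold), which encodes a kinesin of cytokinesis, and CKS2 (1.83-fold). TMPO had another probe at a log2 ratio of 0.25. Adjusted over the list alone, 30 rose and 0 fell, and the list stood out from the other genes (camera with preset correlation, adjusted p = 8.05e-12; 0.0111 with an estimated correlation). Here and below, values with an estimated correlation come from camera on the 8 technical arrays, so they do not measure the spread between cultures. Of 39 immediate early genes, 13 rose and 0 fell, or 27 and 1 adjusted over the list alone (camera adjusted p = 8.05e-12; adjusted p = 0.0111 with an estimated correlation). They included KLF6 (2.30-fold), the antiproliferative gene BTG2 (2.28-fold), IER2 (2.11-fold) and ID1 (1.86-fold), and KLF6 and IER2 were at log2 ratios of 1.01 and 1.03 at their other probes too. Of 31 p53 targets, 10 rose and 1 fell, or 18 and 2 adjusted over the list alone (camera adjusted p = 2.09e-08; adjusted p = 0.0264 with an estimated correlation). PLK3 (2.93-fold), PLK2 (2.35-fold), GADD45B (2.28-fold) and BTG2 led this list, and BTG2 is also counted among the immediate early genes. Over all genes 20 of the 31 p53 targets did not pass by limma, among them CDKN1A, BAX and BBC3. Activity of p53 itself was not measured. Of 43 genes of the G1 to S transition, 8 rose and 1 fell, or 20 and 2 adjusted over the list alone (camera adjusted p = 7.25e-05; adjusted p = 0.0497 with an estimated correlation), with CASP8AP2 (2.48-fold), E2F8 (2.09-fold), ATAD2 (1.81-fold, its other probe at a log2 ratio of 0.24) and the replication inhibitor geminin, GMNN (1.71-fold).

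Another 6 lists were higher by camera with the preset correlation, but were not called by camera on the 8 arrays with an estimated one. The 2 tests also differ in their gene statistics, so the loss cannot be put down to the correlation. For splicing factors and the unfolded protein response the estimated correlation, 0.0018 and -0.0022, was below the preset 0.01. Of 54 replication-dependent histone genes 7 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 0.000398; adjusted p = 0.448 with an estimated correlation), led by H2AC7 (1.99-fold), H2AC4, H2AC17 and H2AC20 (1.53-fold, 1.53-fold and 1.52-fold). Histone genes are near-identical, so their probes may share signal, and the other probe of H2AC20 stood at a log2 ratio of -0.02. Of 30 cell cycle regulators 7 rose and 1 fell, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0023; adjusted p = 0.243 with an estimated correlation). Both activators and inhibitors of the cycle were among those that rose, with the inhibitors CDKN2D (2.20-fold) and CDKN1B (1.73-fold) beside E2F3 (1.87-fold) and E2F2 (1.82-fold, with its other probe at a log2 ratio of -0.17). Of 58 splicing factors and RNA-binding proteins 16 rose and 1 fell, or 21 and 9 adjusted over the list alone (camera adjusted p = 0.00602; adjusted p = 0.275 with an estimated correlation), with SRSF5 (2.02-fold), TARDBP (1.89-fold, its other probes at a mean log2 ratio of 0.05), ZFP36L2 (1.82-fold) and TRA2B (1.80-fold). Of 35 genes of the TGF-beta and BMP pathway 6 rose and 0 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.275 with an estimated correlation), including SKIL (1.95-fold), ID1 (1.86-fold), ID4 (1.54-fold) and SMAD5 (1.4-fold). Of 34 genes of the ATF4 and amino acid response 4 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.243 with an estimated correlation), which were HERPUD1 (2.26-fold), CEBPG (1.93-fold), ATF4 (1.90-fold) and SLC3A2 (1.63-fold). Of 29 genes of the unfolded protein response 3 rose and 0 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.243 with an estimated correlation, and 0.173 without array 3 of replicate 1), which were HERPUD1, DERL2 (1.65-fold) and XBP1 (1.33-fold).

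The lists of oxidative phosphorylation and of cytosolic ribosomal proteins were lower by camera with the preset correlation, but were not called with an estimated one. Fry, which counts the technical arrays as its units and called 25 lists in all, called both lower (adjusted p = 1e-04 and 0.021). Of 73 genes of oxidative phosphorylation 0 rose and 3 fell, NDUFA12 (1.47-fold), COX7B (1.4-fold, its other probe at a log2 ratio of -0.11) and NDUFA7 (1.34-fold), and 12 of the 73 lay above 0. Adjusted over the list alone 0 rose and 0 fell, and the list as a whole was lower by camera (median log2 -0.15, adjusted p = 8.04e-05; adjusted p = 0.0724 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 0 passed the gene test in either direction by limma, over all genes and adjusted over the list alone, and 19 lay above 0. As a list they were lower by camera (median log2 -0.10, adjusted p = 0.0121; adjusted p = 0.448 with an estimated correlation). The direction of this list turned with Agilent's processed signals, to a median 0.01 above that of all genes. RPL22 (log2 -0.34 ± 0.20) and RPS23 (-0.34 ± 0.02) lay lowest (SD, n = 2).

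**Figure D4:**
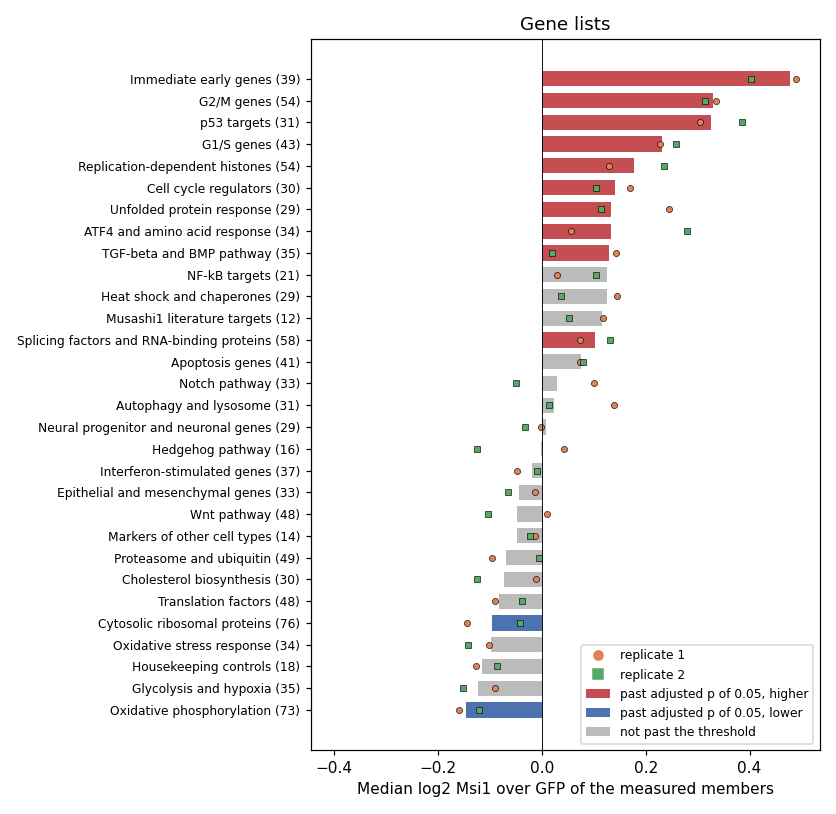
Median log2 ratio of Msi1 over GFP of the measured members of 30 gene lists (bars), with the medians in replicate 1 (orange circles) and replicate 2 (green squares) and the number of measured members in brackets. Immediate early genes had the highest median, 0.48, and oxidative phosphorylation the lowest, -0.15.

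In RNA level, the known Msi1 targets and the pathways linked to Musashi did not stand out from the other genes by camera. Translation and protein levels of these genes were not measured. Another test, fry, asks whether a list's genes move one way on balance and counts the 8 technical arrays of the 2 replicates as its units. It gave adjusted p = 0.023 (up) for the Msi1 targets, 0.015 (up) for the Notch pathway, 0.011 (down) for the Wnt pathway, 0.26 for the Hedgehog and 0.94 for the neural list. Median log2 ratios in the 2 replicates were 0.12 and 0.05 for the Msi1 targets, but 0.10 and -0.05 for the Notch and 0.01 and -0.10 for the Wnt pathway, so in these 2 pathways the replicates went opposite ways. Of 12 measured literature targets of Msi1, NUMB rose and the axon guidance receptor gene ROBO3 fell 1.33-fold (its other probes at a mean log2 ratio of -0.15; camera adjusted p = 0.63), and the counts were the same adjusted over the list alone. In the Notch pathway 2 of 33 genes rose, NUMB and MAML1 (1.31-fold, its other probe at a log2 ratio of 0.08), and the Notch target HES5 fell 1.36-fold (camera adjusted p = 0.802). Its median was above 0 while camera pointed down. In the Wnt pathway 1 of 48 rose, FZD5 (1.45-fold, its other probes at a mean log2 ratio of 0.08), and 1 fell, TLE4 (1.33-fold, its other probe at a log2 ratio of 0.49; adjusted p = 0.26 for the list). In the Hedgehog pathway 0 of 16 passed in either direction by limma (adjusted p = 0.596), with DISP2 at a log2 ratio of 0.64 ± 0.55 and DHH at -0.19 ± 0.07 (SD, n = 2). Among 29 neural progenitor and neuronal genes ROBO3 alone passed, and fell (adjusted p = 0.596). Adjusted over the list alone, 2 Notch genes rose and 1 fell, and 0 genes of the Wnt, Hedgehog and neural lists passed by limma.

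Among the stress and metabolic lists, 4 of 21 NF-kB targets rose and 0 fell, with CXCL2 (1.71-fold), NFKBIA (1.66-fold), IER3 (1.46-fold) and CXCL1 (1.41-fold; camera adjusted p = 0.0618 for the list). The NF-kB list passed in 14 of 25 alternatives, with adjusted p between 0.00611 and 0.255 over all of them. Of 41 apoptosis genes 6 rose and 0 fell, among them BCL2L11 (2.22-fold, its other probes at a mean log2 ratio of 0.19), RIPK1 (1.5-fold) and FAS (1.45-fold; adjusted p = 0.0657), and 14 rose and 2 fell adjusted over the list alone. Of 29 heat shock and chaperone genes 5 rose, among them HSPA8 (1.70-fold), DNAJB4 (1.46-fold) and DNAJA1 (1.42-fold), and HSPA6 fell (adjusted p = 0.185). Of 35 glycolysis and hypoxia genes BNIP3L alone passed, and fell 1.38-fold (its other probe at a log2 ratio of -0.08; adjusted p = 0.094). Of 34 oxidative stress genes 4 rose and 1 fell, with HMOX1 (1.77-fold), NFE2L2 (1.54-fold, its other probe at a log2 ratio of -0.07), SRXN1 (1.53-fold) and SQSTM1 (1.43-fold; adjusted p = 0.497). Of 30 cholesterol biosynthesis genes STARD4 rose 1.42-fold and INSIG1 fell 1.33-fold (adjusted p = 0.319). Of 31 autophagy and lysosome genes 3 rose, ATG16L1 (1.58-fold, its other probe at -0.03 on the log2 scale), SQSTM1 and MAP1LC3B (1.38-fold, its other probes at -0.07), and HEXA fell 1.41-fold (adjusted p = 0.386). Adjusted over the list alone, 5 NF-kB targets rose and 0 fell, 5 chaperone genes rose and 1 fell, 6 oxidative stress genes rose and 8 fell, 8 autophagy genes rose and 1 fell, 1 cholesterol gene rose and 1 fell, and 0 glycolysis genes passed.

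Of 48 translation factors 3 rose and 1 fell (camera adjusted p = 0.63), with EIF5 (2.26-fold), the cap-binding protein gene EIF4E (2.05-fold), EIF4A2 (1.72-fold) and EIF4G3 (1.43-fold lower, its other probe at a log2 ratio of -0.07). Of 49 proteasome and ubiquitin genes 3 rose and 0 fell, PSMD7 (1.83-fold), FBXW7 (1.62-fold, its other probe at 0.14 on the log2 scale) and PSMD12 (1.56-fold, its other probes at a mean log2 ratio of 0.08; adjusted p = 0.726). In the epithelial and mesenchymal list 3 of 33 rose, SNAI1 (1.65-fold), OCLN (1.5-fold) and TGFBR2 (1.36-fold), and 2 fell, one of them at the CLDN3 probe described above (adjusted p = 0.708). Of 37 interferon-stimulated genes IRF7 rose 1.46-fold and IFI27 fell 1.55-fold (adjusted p = 0.386). Markers of other cell types gave 0 of 14 genes past the threshold by limma (adjusted p = 0.381), with ALB at a log2 ratio of -0.32 ± 0.05 and CD79A at -0.14 ± 0.17. Of 18 housekeeping genes 0 passed by limma (adjusted p = 0.26), with PPIB at -0.36 ± 0.03 and TFRC at 0.34 ± 0.53 (SD, n = 2). In these 6 lists the counts adjusted over the list alone equalled those over all genes.

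A few list members outside the rule for named genes complete the small counts above and were chosen after their values were seen. The single genes that fell were RAD51AP1 among the G1 to S genes (1.45-fold), the retinoblastoma gene RB1 among the cell cycle regulators (1.67-fold, its other probes at a mean log2 ratio of -0.05), CCNG1 among the p53 targets (1.34-fold), the splicing regulator RBFOX2 (1.66-fold) and PGD among the oxidative stress genes (1.37-fold). ACTA2 was the other epithelial or mesenchymal gene that fell (1.32-fold). DNAJB6 (1.37-fold) and HSF2 (1.36-fold) were the remaining chaperone list genes that rose, with other probes at mean log2 ratios of 0.06 and 0.11.

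The changes in the 2 replicates were correlated. Across the 20667 genes, which are not independent replicates, their log2 ratios correlated with Pearson r = 0.775 and Spearman rho = 0.668, and 72.9% of genes had the same sign. The SD of log2 ratios was 0.354 in replicate 1 and 0.297 in replicate 2. Of the 47 genes at least 2-fold lower, 42 changed more in replicate 1, as did 206 of the 274 genes lower by under 2-fold. Single arrays of one replicate correlated at r = 0.83 to 0.94 with the same dye orientation and at 0.40 to 0.61 with the opposite one. Arrays of different replicates correlated at 0.63 to 0.78 with the same orientation and at 0.32 to 0.57 with the opposite one, so orientation separated the arrays more than replicate did.

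A purely technical contrast was tested in the same way. The dye effect was the difference between the 2 orientation means divided by 2. It gave 1309 genes past the adjusted p of 0.05 by limma, 566 brighter in Cy5 and 743 in Cy3. Its SD over genes was 0.16, against 0.307 for the Msi1 effect. Without background subtraction 0 genes passed for dye, and with median centring 4891 did. Each replicate held both orientations equally, so a dye effect that is equal on its arrays cancels in the replicate means. Still, 163 genes were called both for dye and for Msi1, against 108 for independent lists. Across genes the dye and Msi1 effects correlated at 0.2.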

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

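The tests of explanations for the background fit, the lower genes and the higher lists were all chosen after those results were seen. Of 112 sets of 8 array values examined for an array far from the others, 6 had one, against 5.6 that chance would give.

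The background model fitted to array 4 of replicate 1 stood far from the other seven. Its background mean was -316 in Cy3, against -7.70 to -2.05 on the others, and -153 in Cy5, against -11.3 to -4.65. The SD of log2 ratios on this array was 0.244, against 0.351 to 0.379 on the other arrays of the replicate. With the background parameters of its partner array it became 0.356, which is what a poor background fit would give and a candidate explanation. Weak hybridisation is argued against, since without background subtraction the SD was 0.35, against a lowest value of 0.342 on the other three. The arrays of a replicate share their RNA extracts, so no biological explanation was tested, and the authors' deposited values carry the same narrow ratios.

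Of the 47 genes at least 2-fold lower in Msi1, 12 had another measured probe, and in these the other probes kept a median share of 0.00942 of the change. The median log2 ratio at the other probes of these 12 genes was -0.0298, so the fall was not seen there. Those probes are dimmer by rule, and their brightness was not compared. The values thus argue against a lower transcript level only as far as these probes could show one, and a change in one isoform stays open. For the 35 genes with no other measured probe, a lower transcript level and a probe-specific signal cannot be told apart. Background correction is argued against too, as the median without background subtraction was -2.04 and 47 of 47 stayed at least 2-fold lower. A hypothesis is that some of these probes bind the abundant GFP transcript of the control cells, but probe sequences were not searched.

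The immediate early, G2 and M phase and p53 lists were higher in both replicates. Brightness of the probes is argued against, since the lowest of their 3 percentiles among 10000 random lists of like brightness was 100. A dye effect is argued against, since the lowest of the 6 medians by list and orientation was 0.275. A signal of single probes stays open. Over the 42 members with another probe the median log2 ratio was 0.394 at the tested probe and 0.162 at the others, a ratio of 0.411. The other probes are dimmer by rule and the cut-offs for this ratio were set after the values were seen, so it cannot decide. An effect of Msi1 and any other difference between the 2 transfected cultures were not tested against each other.

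The remaining arrays that stood apart concern single genes. CXCL2 stood at a log2 ratio of 0.287 on array 4 of replicate 1, against 0.757 to 1.00 on the others. RPS23 stood at -0.857 on array 4 of replicate 2, against -0.429 to -0.092. INSIG1 stood at -0.659 on array 1 of replicate 2, against -0.446 to -0.301. NFE2L2 stood at 0.98 on array 4 of replicate 2, against 0.492 to 0.641.

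The labelling spike-in controls, which the comparisons do not use, had a mean log2 ratio of Msi1 over GFP of -0.412 in replicate 1, with 10 of 10 transcripts below 0, and -0.08 in replicate 2, with 9 of 10 below 0. Single arrays lay between -0.62 and -0.30 in replicate 1 but went both ways in replicate 2, at 0.20, 0.08, -0.47 and -0.14. The median gene was thus 0.41 above the spike-ins in replicate 1, while the mean of replicate 2 was small against the spread of its arrays.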

How the results depend on the processing

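Another background fit for array 4 of replicate 1, centring on spike-in controls and the dimmest probe were chosen after the data were seen. Against 1698 called genes, 1377 higher and 321 lower, Agilent's processed signals gave 507 (427 and 80), no filter on dim probes 580 (541 and 39), the strict filter 3204 (2194 and 1010) and median centring 1053 (121 lower). A variance trend with robust moderation gave 473 (473 and 0). A threshold of 0.10 gave 4266 (2659 and 1607). Treating arrays as the unit, which measures mostly technical spread, gave 6227 (3554 and 2673) with slide as a random block, 8506 (4489 and 4017) with independent arrays, 8357 (4427 and 3930) in replicate 1 alone and 9197 (4950 and 4247) in replicate 2 alone. The random-block fit held no dye term, unlike the fits of independent arrays and of single replicates, and its estimated correlation within slides was -0.000584. These counts therefore differ by more than the unit. Arrays with Msi1 in Cy5 gave 3431 (2068 and 1363), and those with Msi1 in Cy3 gave 628 lower. The other background fit for array 4 of replicate 1 gave 558 lower, centring on spike-ins 2999 (2911 and 88) and the dimmest probe 983 (816 and 167). With one array left out, calls ranged from 1406, without array 4 of replicate 2, to 2936, without array 4 of replicate 1, the higher from 1176 to 2104 and the lower from 230 to 832. The cause was not tested, except that the unit of replication and the thresholds act by construction. Of the 1698 genes, 0 changed direction under background, normalization or centring alternatives. With only the arrays that had Msi1 in Cy5 7 did, with only those that had it in Cy3 2, and with the strict filter 1. With the mean of all probes 7 did and with the dimmest probe 141, where only the 717 with another measured probe could.

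The MSI1 log2 ratio of 0.255 passed the threshold with arrays as the unit (0.255 with the random block and with independent arrays, and 0.358 in replicate 2 alone) but not in replicate 1 alone (0.152, adjusted p = 0.0543), and without either replicate it was 0.152 to 0.358. Centred on spike-ins it was 0.501 (adjusted p = 0.061). Agreement between replicates stayed between 0.709 and 0.804 in all alternatives run. Camera on the 8 technical arrays with an estimated correlation left 4 of 12 lists, and fry on the same arrays called 25. With the other alternatives between 10 and 14 lists passed. Of 25 alternatives, the unfolded protein response lost its call in 6 (adjusted p up to 0.32), splicing factors in 4 (0.062), the ATF4 response in 2 (0.69), ribosomal proteins in 2 besides the one that turned them, the TGF-beta pathway in 1 (0.136) and cell cycle regulators in 1 (0.0596). A call was gained by NF-kB targets in 14, apoptosis genes in 4, glycolysis genes in 2, and the Wnt, translation, epithelial and housekeeping lists in 1 each. The dye effect, 1309 genes, became 0 without background subtraction, 0 with Agilent's processed signals, 4891 with median centring and 695 with the authors' values.

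Named genes turned direction almost only with the dimmest probe. FCRLB became 0.071, TLX2 0.0033, FZD5 -0.031, TLE4 0.49, E2F2 -0.17, H2AC20 -0.015, PSMD12 -0.51, TARDBP -0.30, NFE2L2 -0.069, ATG16L1 -0.030 and MAP1LC3B -0.087. TLE4 became 0.037 with the mean of all probes, DHH 0.060 and CD79A 0.11 with spike-in centring and TFRC -0.040 in replicate 2 alone. Among the lists, by their median relative to all genes, ribosomal proteins turned with Agilent's processed signals (0.015, adjusted p = 0.719 within a range of 2.99e-11 to 0.719). The other lists that turned were not called in the main comparison. In replicate 2 alone the Notch pathway became -0.043, the proteasome 0.0023, neural genes -0.026 and the Hedgehog pathway -0.12. In replicate 1 alone the Wnt pathway became 0.014. With Msi1 in Cy3 the Notch pathway became -0.025, the Wnt pathway 0.0069, cholesterol genes 0.0056, the Hedgehog pathway -0.056 and housekeeping genes 0.038. With Msi1 in Cy5 translation factors became 0.0015, neural genes -0.0047 and housekeeping genes 0.016. Median centring turned cholesterol genes (0.0072), neural genes (-0.0020) and the Hedgehog pathway (-0.021). Without a filter interferon-stimulated genes became 0.0036 and the Hedgehog pathway -0.0013, and with the strict filter neural genes became -0.048 and epithelial genes 0.0075. The Hedgehog pathway became -0.011 with the mean of all probes and -0.0011 with the dimmest. With single arrays left out, neural genes ranged from -0.018 to 0.020 (-0.0093 without array 1 of replicate 2), the Hedgehog pathway from -0.014 to 0.013 (-0.012 and -0.0087 without arrays 2 and 3 of replicate 2) and autophagy genes from -0.0010 to 0.065. Signal over background limits dim genes, since only probes above background in one of the channels on 4 arrays or more were tested.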

Other observations

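Members of 10 gene families were also counted, against 1377 of 20667 higher over all genes. Some members, among them KLF2, KLF6 and DNAJB4, are also in the fixed lists, so these counts partly repeat the results above. The families were chosen after their values were seen and were not tested for enrichment. Of 393 measured genes named ZNF, which encode zinc finger proteins, 85 rose and 1, ZNF600, fell (2.53-fold). ZNF200, ZNF614 and ZNF256 led them at 3.17-fold, 3.12-fold and 2.99-fold. Of 36 ZBTB genes 7 rose and 0 fell, among them ZBTB10 (1.82-fold, its other probe at a log2 ratio of -0.03) and ZBTB43 (1.63-fold). Of 12 SNHG genes, which host small nucleolar RNAs, 4 rose and 0 fell, SNHG12 (2.00-fold), SNHG15 (1.99-fold), SNHG8 (1.58-fold, its other probes at a mean log2 ratio of -0.12) and SNHG1 (1.56-fold). Of the 6 CLK and CCNL genes, which encode splicing kinases and cyclins, CCNL1 (2.50-fold), CLK1 (1.74-fold) and CLK4 (1.37-fold) rose. DNAJ co-chaperone genes had 8 of 38 higher, led by DNAJC27 (2.65-fold), and KLF genes 2 of 15. Over the 17 DNAJ genes with another measured probe the median log2 ratio was 0.281 at the tested probe and -0.019 at the others, and over 7 such KLF genes it was 0.306 and -0.012. For ZBTB genes these medians were 0.142 and 0.052, for SNHG genes 0.32 and 0.186, and for CLK and CCNL genes 0.376 and 0.26. HOX genes, mitochondrial ribosomal proteins, solute carriers and tRNA synthetases had medians of 0.02, -0.0043, -0.0026 and -0.07, and 2 of 34, 1 of 77, 15 of 275 and 0 of 17 rose.

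A rise of the ZNF genes as a family stays an untested hypothesis, because the family was chosen for these values. Their median log2 ratio was 0.17, and its percentile of 100 among 10000 random lists of like brightness only restates that choice. Relative to all genes the family stood 0.19 higher without background subtraction, 0.33 with Agilent's processed signals and 0.22 with median centring. A signal of single probes stays open as part of the cause. Over the 133 ZNF genes with another measured probe, the median was 0.233 at the tested probe and 0.069 at the others, a ratio of 0.296. Here too the other probes are dimmer by rule, so this ratio cannot decide. Both tests were chosen after the family was seen. Of these 133, 96 lay above 0 at their other probes.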
